A study of Mus musculus with 10 samples.

How the data were processed

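Gene expression was measured in the prefrontal cortex of male DBA/1 mice with 2-colour oligonucleotide arrays printed in-house, in a direct comparison of collagen-immunised (arthritic) with control mice on every array. Per the labels' protocols, mice were 8 weeks old. Controls received 200 µl of Complete Freund's adjuvant and collagen mice 100 µl of type II collagen in 100 µl of the same adjuvant, and both arms received LPS at day 24. The time of sacrifice in the labels carries the number 31 and can be read as a day or as an hour, so it was not used. Total RNA was reverse transcribed with aminoallyl-dUTP and coupled to Cy3 or Cy5. Both arms had adjuvant and LPS, but collagen mice had the smaller volume of adjuvant, so the ratio holds collagen and the adjuvant dose together.

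The 10 arrays form 5 dye-swap pairs, with collagen on Cy5 on 5 arrays and on Cy3 on the other 5. The titles number the pairs 1, 2, 3, 1 and 2, here called pairs 1 to 5, and the series text states 3 biological replicates. Pairs 1 and 4 were therefore averaged into replicate 1 and pairs 2 and 5 into replicate 2, and pair 3 alone was replicate 3. Nothing in the labels says how many mice stand behind a number or whether the second pair of a number used the same RNA. If a number does not stand for separate animals, p-values measure only the spread between these values, which may be technical. Across probes, pairs of the same number correlated at 0.0913 and 0.142, and pairs of different numbers at 0.0935 on average.

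Each array came with 3 deposited files, taken as repeat readings at rising gain because the intensities grew from reading 1 to reading 3 by a factor of 1.93 to 2.42 in pairs 1 to 3 and 4.19 to 4.61 in pairs 4 and 5. Per the file headers, each file holds a spot intensity corrected for background in channel A and in channel B, the local background and a flag. The scanner, the image software and its version are not given in the sources used here. Spots flagged X or Z held an intensity of 0 in all files and spots flagged Y lay at or below background. Flags B, C and S were kept, and the file headers do not define the letters. A reading covered 10080 spots in 12 by 4 grids of 14 by 15 spots. The kept share per reading was 75.5% to 94.0% in channel A and 32.0% to 79.8% in channel B.

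The deposited intensity columns already had the background taken off, so no further correction was made. The normexp correction with offset 50 that had been chosen before the data were examined was run as an alternative instead. Log2 ratios of channel B over channel A were normalised within each reading by limma's global loess (span 0.3), and the 3 readings of an array were averaged. The readings of an array correlated at 0.635 to 0.908 across spots after loess. Ratios were turned to collagen over control, averaged over the 2 arrays of a pair (both were needed) and then over the pairs of a replicate with equal weight.

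The files do not state which dye each channel letter stands for. Channel A was taken as Cy3 and channel B as Cy5, so every direction given here is likely rather than settled. The basis is the order of the channels in the labels, and a background that was higher in channel A than in channel B on all 10 arrays, by a factor of 1.07 to 2.42, whichever sample the channel held. Neither settles the assignment. The authors' deposited table was set against ratios turned this way after print-tip loess, a loess fitted to each grid by itself. It correlated with them at 0.725 to 0.908 on the 10 arrays, which does not help, since its direction is not given in the sources used here. If the letters are the other way round, every sign reverses and every size stays.

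The authors' deposited table of processed values holds 1 score per spot and array, a log ratio whose base, normalisation and combination of readings are not given in the sources used here. Its medians per array lie between -0.00553 and 0.00457, and at large ratios it was 0.356 to 0.706 times the log2 ratio of the readings after print-tip loess. Its medians put its centre near 0. If channel A is Cy3 it runs as collagen over control, and its base stays unsettled. It served only as an alternative.

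Spots were numbered by grid row, grid column, row and column. The platform table gave 9066 probes 1 gene symbol and 12 probes several, and did not list 1002 spots, which were left out because control spots were not marked in the files. That rule was set after the files were seen, and all 10080 spots were run as an alternative. Symbols were updated through Entrez IDs with the RefSeq gene table of GRCm38.p6, which held 99.0% of the probes with 1 symbol. The sources name no genome build for the array, so no coordinates are given.

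Probes with a value in all 3 replicates, 4125 in number, were fitted with an intercept in limma (lmFit and eBayes, two-sided, R 4.3.3, limma 3.58.1, statmod 1.5.0), with Benjamini-Hochberg adjustment. SE is limma's moderated standard error. A list of 20 gene sets and 14 sets of cell type and region markers was fixed before the data were examined. Sets with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with the brightest probe for each gene, and adjusted over all sets tested. Camera with an estimated correlation and fry were alternatives. The same fit on Cy5 over Cy3, without turning the swapped arrays, measured the dye effect.

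Genes to be named were chosen by a rule fixed beforehand. It took up to 12 genes in each direction past an adjusted p of 0.05 with the same sign in all 3 replicates, filled to 8 by the smallest p where fewer passed. It added the 4 members with the smallest p of each set past its test, and Il1b, Tnf, Il6, Ptgs2, Lcn2, C3, Gfap, Aif1, Nr3c1, Fkbp5, Fos and Bdnf where measured. RIKEN, Gm, LOC and clone names were passed over.

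The fit was tested on simulated data with 4125 probes and 3 replicates, with spreads taken from this comparison. It called 35.9% of probes changed by 0.5 on the log2 scale, 94.0% of those changed by 1 and 99.5% of those changed by 2, with 4.86% false calls. Each simulation changed many probes at once, which eases the adjustment, so these rates need not hold where few genes change. Camera found a list of 27 genes moved by 0.2 in 20 of 20 simulations, with members drawn independently. The sets called below had medians of 0.083 to 0.107 and estimated correlations of 0.131 to 0.176, a case that these simulations did not cover. For arrays, their number limits the precision.

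Alternatives concerned the background, the normalisation (print-tip loess, median centring, scaling between arrays), filters on dim probes, single readings, the unit of replication with the replicate number as a block, single dye orientations, the first 3 pairs, each replicate left out, the variance model and the authors' values. Plain background subtraction was the same as the values used and gave nothing to compare.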

Results

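The series asked how gene expression in the prefrontal cortex of arthritic DBA/1 mice differs from that of control mice. DBA/1 is an inbred strain that develops arthritis after immunisation with type II collagen. Each of 10 arrays carried collagen and control RNA together, in 5 dye-swap pairs that stand for 3 replicates. Both channels were measured on 44.5% to 85.1% of the spots of an array. Of 9078 listed probes, 4125 had a ratio in all 3 replicates and stood for 4033 genes. Ratios are collagen over control, and their direction is likely rather than settled, since the files do not tie the channel letters to the dyes and the order of the channels in the labels was followed.

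No gene passed the adjusted threshold in the comparison of arthritic with control cortex, and nearly all differences were small. The log2 ratio lay under 0.5 in size for 99.6% of probes. The lower genes with the smallest p began with Efhc2, which encodes an EF-hand protein of cilia, at -0.74 (SE 0.11, n = 3 replicates, from pairs 3, 4 and 5), and the adhesion glycoprotein gene Smagp at -0.56 (SE 0.11). The focal adhesion gene Tes followed at -0.53 (SE 0.12). On the higher side stood Fap, which encodes the serine protease fibroblast activation protein, at 0.90 (SE 0.20; 0.37 with print-tip loess), and Sdhaf2, an assembly factor of succinate dehydrogenase, at 0.56 (SE 0.15). None of these passed limma's test after Benjamini-Hochberg adjustment (adjusted p = 0.642 for each, which was also the lowest of all probes).

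The other higher genes by the smallest p were Arnt, the dimer partner of the aryl hydrocarbon receptor, at 0.50 (SE 0.10), and Cldn10, a claudin of tight junctions, at 0.43 (SE 0.12). They included Rev1, a translesion DNA polymerase, at 0.42 (SE 0.09), and Marchf8, a membrane-bound ubiquitin ligase, at 0.37 (SE 0.09). Coch, which encodes cochlin, had 0.36 (SE 0.09), and Mal, a proteolipid gene of myelin, 0.35 (SE 0.09). The other lower genes were Ttc7 at -0.49 (SE 0.12) and Sesn3, a stress-induced sestrin, at -0.46 (SE 0.11). Lower too were the forkhead factor Foxk1 at -0.43 (SE 0.10), the ciliogenesis gene Fuz at -0.41 (SE 0.09) and the spermatid protamine Prm3 at -0.39 (SE 0.09). All 16 had the same sign in all 3 replicates, as the rule required, and the adjusted p by limma was 0.642 for each. Only 3 of the 8 higher and 2 of the 8 lower genes were measured in all 5 pairs. The others rest on fewer pairs, and Mal read -0.02 in pair 1, so its sign held only after averaging. Second probes of Tes and Cldn10 read 0.16 and 0.01. With print-tip loess, which fits each grid of the array by itself, all 8 higher genes and 5 of the 8 lower genes shrank by over 1.5 times, among them Mal to 0.16, Coch to 0.22, Sesn3 to -0.15 and Prm3 to -0.14.

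limma called 0 probes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 98 higher and 170 lower, 268 in all, against the 206 that 5% of the probes makes. With median centring in place of loess the same counts were 23 and 121, and the total was 158 of 2778 probes without pair 4 and 119 of 2595 without pair 5. Without replicate 3 there were 214 higher and 155 lower, so the balance turned. A single gene passed in some other settings: Fap with scaling between arrays (log2 ratio 0.97, adjusted p = 0.0324), Tes on the 10 arrays with the replicate number as a block (-0.46, adjusted p = 0.0486) and Efhc2 in the authors' values (adjusted p = 0.0195). The block had a consensus correlation of -0.145, so it did not allow for likeness between arrays of a replicate, and with a dye term beside it no gene passed (lowest adjusted p = 0.142). The ratio had the same sign in all 3 replicates for 35.2% of probes, where independent replicates centred on 0 would give 25%. The replicates correlated at 0.136 on average, and at 0.0544 with print-tip loess, so place on the array enters that share. The difference from 25% therefore cannot be ascribed to collagen. The median SD between replicates was 0.17 on the log2 scale. On simulated data with this spread, in which many probes changed at once, the fit called 94.0% of probes changed by 1 and 35.9% of those changed by 0.5. With few changed probes the adjustment is harder to pass, so 0 calls do not exclude single changes of that size. The only tested probe with a ratio of 1 or more, for Xist at 1.09, had an adjusted p of 0.642 by limma.

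**Figure D1:**
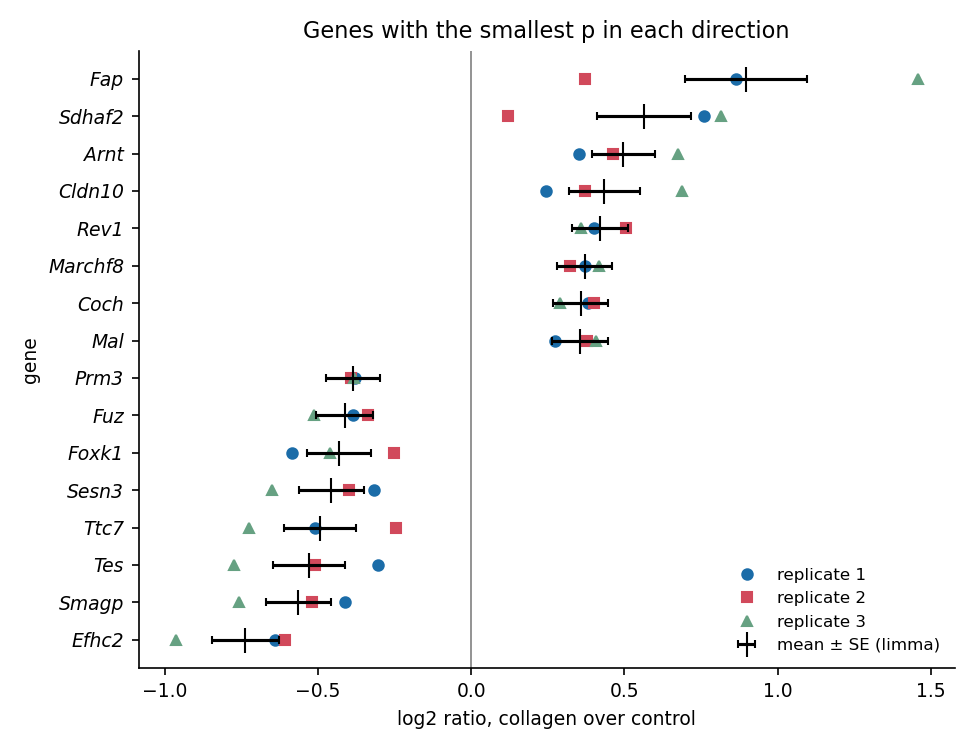
Log2 ratio of collagen over control (x axis) for the 16 genes with the smallest p in each direction (y axis). Coloured symbols are the 3 replicates and black bars the mean with limma's SE. The means run from -0.74 for Efhc2 to 0.90 for Fap, and the 3 replicates of Prm3 lie closest together.

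Of the 12 genes named in advance for inflammation, glia, stress and activity, 7 had a probe and 3 were measured in all replicates. The cytokine gene Il1b had a log2 ratio of 0.11 (SE 0.09), the immediate early gene Fos -0.07 (SE 0.16) and the neurotrophin gene Bdnf -0.03 (SE 0.11). Their adjusted p-values by limma were 0.684, 0.892 and 0.932. The probes for Il6, Lcn2, Aif1 and Fkbp5 lacked a value in at least 1 replicate and were not tested. With print-tip loess the ratio of Il1b was 0.02 and that of Fos 0.03, on the other side of 0.

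Gene sets showed small shifts in 3 cases of 22 tested, all on the higher side by the mean of the replicates. Ribosomal protein genes were higher in 24 of 27, with a mean of the replicate medians of 0.11 ± 0.05 (SD, n = 3) and an adjusted p of 0.00101 by limma's camera. Oxidative phosphorylation genes were higher in 25 of 30 (0.08 ± 0.11, adjusted p = 0.0137). Antioxidant defence genes were higher in 13 of 15 (0.08 ± 0.08, adjusted p = 0.0255). With normexp, the correction chosen before the data were examined, antioxidant defence did not pass (median over genes 0.128, adjusted p = 0.0816 by limma's camera). In replicate 2 the median was 0.059 for ribosomal proteins, but -0.047 for oxidative phosphorylation and -0.003 for antioxidant defence. With an estimated correlation none of the 3 passed (adjusted p = 0.915 for each). The medians over the genes of the 3 sets were 0.107, 0.083 and 0.096. Without replicate 1 they were 0.080, 0.037 and 0.051 (adjusted p = 0.333, 0.543 and 0.666 by limma). Without pair 4 they were 0.043, 0.063 and 0.055 (adjusted p at 0.212 or above for all 3 by limma's camera). Only 20, 17 and 10 genes were then measured, so the fall mixes fewer genes with fewer arrays. Without replicate 2 the medians of oxidative phosphorylation and antioxidant defence were 0.134 and 0.151. The adjusted p by limma's camera without replicate 3 was 0.0855 for oxidative phosphorylation and 0.286 for antioxidant defence. Without pair 5 antioxidant defence had a median of 0.050 over the 10 genes then measured and an adjusted p of 0.152. Over all alternatives the adjusted p ran from 2.22e-07 to 0.915 for ribosomal proteins, from 1.62e-06 to 0.915 for oxidative phosphorylation and from 0.00701 to 0.948 for antioxidant defence. No member of these sets passed alone, whether over all genes or adjusted over the list alone (0 of 72 in each case).

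Among ribosomal proteins, Rpl32 stood at 0.18 (SE 0.09), Rpl11 at 0.17 (SE 0.09), Rps12 at 0.17 (SE 0.09) and Rpl37 at 0.16 (SE 0.09). The respiratory chain members were Uqcrq of complex III at 0.23 (SE 0.11), Cox6c of complex IV at 0.21 (SE 0.11), and Ndufv2 and Ndufb10 of complex I at 0.20 (SE 0.09) and 0.17 (SE 0.09). Second probes of Uqcrq and Rpl11 read 0.05 and 0.00. With print-tip loess Ndufv2 had 0.06, Ndufb10 0.01, Uqcrq 0.10 and Rps12 0.04, and Gstm5 of the antioxidant set 0.07. For antioxidant defence the members were the metallothioneins Mt1 and Mt3, at 0.21 (SE 0.10) and 0.17 (SE 0.11), and the glutathione transferases Gstm1 and Gstm5, at 0.17 (SE 0.09) and 0.16 (SE 0.09). The adjusted p of these 12 members lay between 0.642 and 0.652. On arrays with collagen on Cy3 alone the medians of the 3 sets were negative, at -0.12 for ribosomal proteins, -0.11 for oxidative phosphorylation and -0.0480 for antioxidant defence. On arrays with collagen on Cy5 alone they were 0.33, 0.29 and 0.15. With no background correction they were 0.051, 0.019 and 0.019, with adjusted p-values by limma of 0.154, 0.328 and 0.260.

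Glutamate signalling genes came closest to the threshold on the lower side, with 6 of 8 lower, a mean of replicate medians of -0.20 ± 0.22 (SD, n = 3) and an adjusted p of 0.05004 by limma's camera. Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase II, had a log2 ratio of -0.37 (SE 0.09), and Dlg4, the postsynaptic density scaffold, -0.44 (SE 0.12). These 2 passed adjusted over the list alone, and 0 passed over all genes. With print-tip loess Dlg4 still did (-0.39, adjusted p = 0.0284 over the list alone by limma), but Camk2a did not (-0.23, adjusted p = 0.0702). The set's median over genes went from -0.25 to -0.06 with print-tip loess (adjusted p = 0.0959 by camera). Without replicate 3 it was -0.14 over the 12 genes then measured (adjusted p = 0.0855), and without replicate 2 the adjusted p was 0.0346. Over the alternatives the set's adjusted p ran from 0.0167 to 0.948. With an estimated correlation the adjusted p was 0.915. Camk2a and Dlg4 fall outside the naming rule and were chosen after their values were seen. Synaptic vesicle genes were lower in 14 of 17 (-0.08 ± 0.08, adjusted p = 0.345), which did not pass, and their median over genes went from -0.084 to -0.030 with print-tip loess.

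Sets of inflammation and stress did not pass. Of the 5 measured chemokine genes 5 were lower (-0.06 ± 0.02, adjusted p = 0.345, and 0.0473 without pair 5), and of the 5 acute phase and LPS response genes 3 were higher (0.08 ± 0.03, adjusted p = 0.480). Complement genes were divided 3 and 3 (adjusted p = 0.905), and genes of the glucocorticoid response and stress axis 4 and 4 (adjusted p = 0.905). Microglia and macrophage markers were lower in 5 of 6 (-0.16 ± 0.20, adjusted p = 0.345, and 0.0292 with median centring) and oligodendrocyte and myelin markers in 3 of 7 (-0.04 ± 0.08, adjusted p = 0.905). Without replicate 3 the median over the microglia and macrophage genes was -0.075 over the 9 genes then measured, against -0.157 over 6 with it. Astrocyte markers had a mean of replicate medians of -0.01 ± 0.16, excitatory neuron markers 0.01 ± 0.06 and interneuron markers 0.08 ± 0.15, each with an adjusted p of 0.905. Markers of striatum, the region next to the cortex, were lower in 5 of 5 (-0.12 ± 0.10, adjusted p = 0.345), but their median over genes went from -0.105 to -0.018 with print-tip loess (adjusted p = 0.945), with Tac1 above 0. With an estimated correlation the adjusted p of chemokines and of microglia, on the loess values of all pairs, was 0.915. The adjusted p-values before that are from limma's camera with the preset correlation, and 0 of the members of these sets passed adjusted over the list alone.

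The remaining tested sets had mean replicate medians close to 0 and did not pass by limma's camera. These were immediate early genes (0.03 ± 0.06, adjusted p = 0.720), GABA signalling (-0.03 ± 0.03), monoamine and acetylcholine signalling (-0.05 ± 0.08) and neuropeptides, opioids and cannabinoids (-0.01 ± 0.00). The last of them were neurotrophic factors (0.00 ± 0.07), heat shock proteins and chaperones (-0.01 ± 0.03) and apoptosis (0.01 ± 0.03), and GABA and these later sets had an adjusted p of 0.905. For GABA signalling the median over genes was further from 0, at -0.104 with 5 of 8 lower, and 0.005 with print-tip loess. The median, the mean, the mean of replicate medians and the test differed in sign in 8 of the 22 sets, namely neuropeptides, neurotrophic factors, heat shock proteins, apoptosis, excitatory neurons, interneurons, astrocytes and oligodendrocytes.

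The other 12 sets had under 5 measured genes and no test. The median log2 ratio was -0.14 over 4 genes of cytokines and their receptors, -0.16 over 4 interferon response genes and -0.19 over 2 genes of tryptophan and kynurenine metabolism. It was -0.03 over 4 oligodendrocyte precursor markers, -0.05 over 4 endothelial markers and -0.28 over 3 markers of pericytes, muscle and fibroblast cells of vessels and meninges. It was -0.08 over 2 neutrophil markers, -0.18 over 3 lymphocyte markers, -0.15 over 2 markers of choroid plexus and ependyma and 0.07 over 4 olfactory bulb markers. Of MHC and antigen presentation, 2 of 23 genes had a probe and 0 were measured in all replicates. Of the erythroid set, 0 of 12 genes had a probe, so neither set tells of its signal. Among the vessel markers 1 of the 3, Pdgfrb, passed adjusted over the list alone (-0.38, SE 0.12). It lies in grid row 2 and did not pass with print-tip loess (-0.14, adjusted p = 0.361 over the list alone by limma), and it was chosen after its values were seen. Print-tip loess moved 7 of these 10 medians by over 1.5 times, to -0.079 for cytokines, -0.075 for interferon response, -0.124 for vessel markers and -0.059 for lymphocytes. It took those of oligodendrocyte precursors to -0.0063, endothelial markers to 0.0045 and neutrophils to 0.026, the last 2 across 0.

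**Figure D2:**
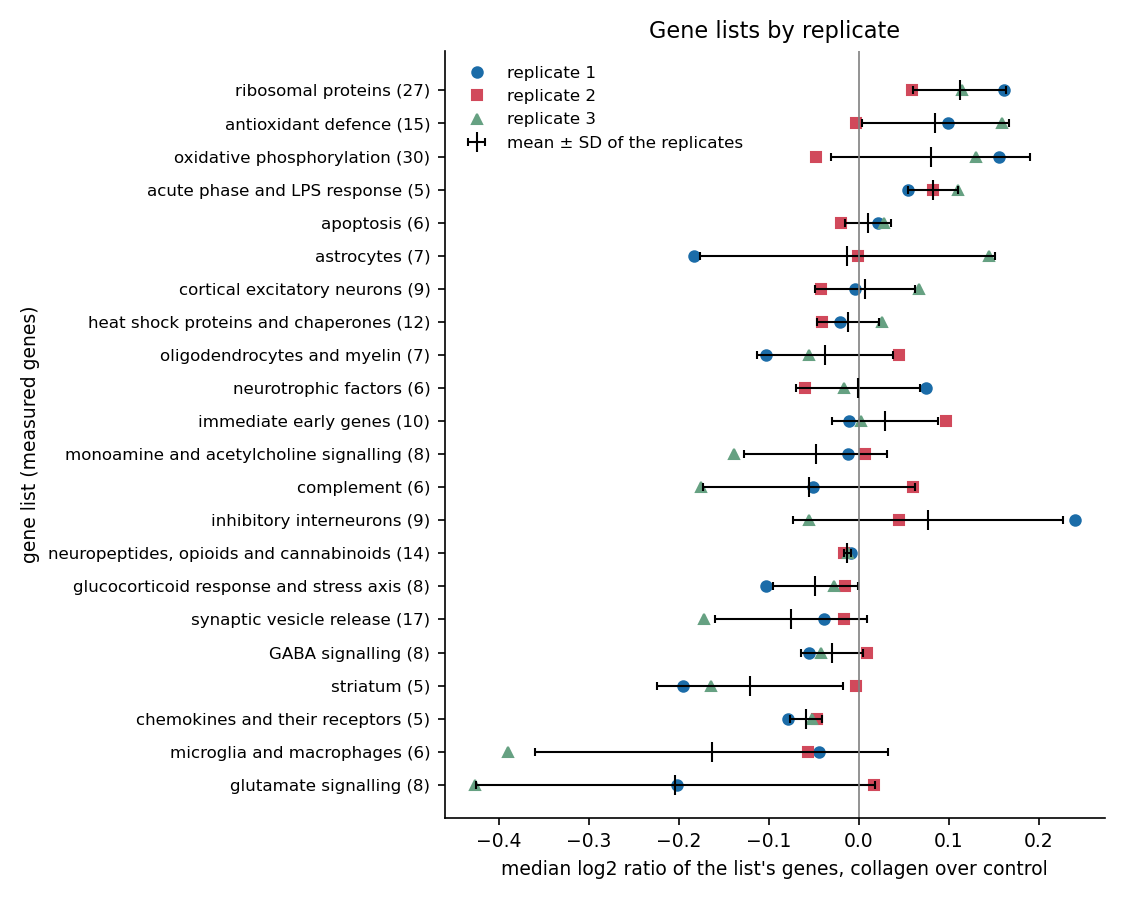
Median log2 ratio of collagen over control (x axis) in each of the 22 tested gene sets, with the number of measured genes in brackets (y axis). Coloured symbols are the 3 replicates and black bars their mean and SD. The ribosomal protein set lies above 0 in all 3 replicates, and glutamate signalling reaches -0.43 in replicate 3.

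The replicates had little in common. The log2 ratios correlated between replicates at 0.0774, 0.129 and 0.201 across probes, which are not independent. Their mean of 0.136 became 0.0544 with print-tip loess and -0.00943 with median centring. Cy5 over Cy3, before turning, correlated at 0.161 to 0.685 between the 2 arrays of a pair. The SD over probes of the dye effect was 0.42 and that of collagen over control 0.27, on average over the 5 pairs. The same limma fit on the dye effect called 74 probes at an adjusted p under 0.05 and 842 at an unadjusted p under 0.05. The former count was 255 with no background correction, 46 with probes above background on every array, 40 with normexp and 21 with median centring.

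The ratio depended on the place on the array. The median log2 ratio was -0.15 in grid row 1, -0.13 in row 2 and -0.11 in row 3, and 0.08 in row 8. Rows 1 to 3 held 27.8% of the probes and 124 of the 170 lower calls at an unadjusted p under 0.05, and 6 of the 8 named lower genes. With print-tip loess the counts at an unadjusted p under 0.05 were 73 higher and 100 lower. The 8 named lower genes then lay between -0.59 and -0.14 and the 8 higher between 0.16 and 0.37. The 3 gene sets passed with print-tip loess as well, with adjusted p-values by limma of 4.62e-06, 0.00193 and 0.0102, but not with an estimated correlation (adjusted p = 0.899 for each).

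**Figure D3:**
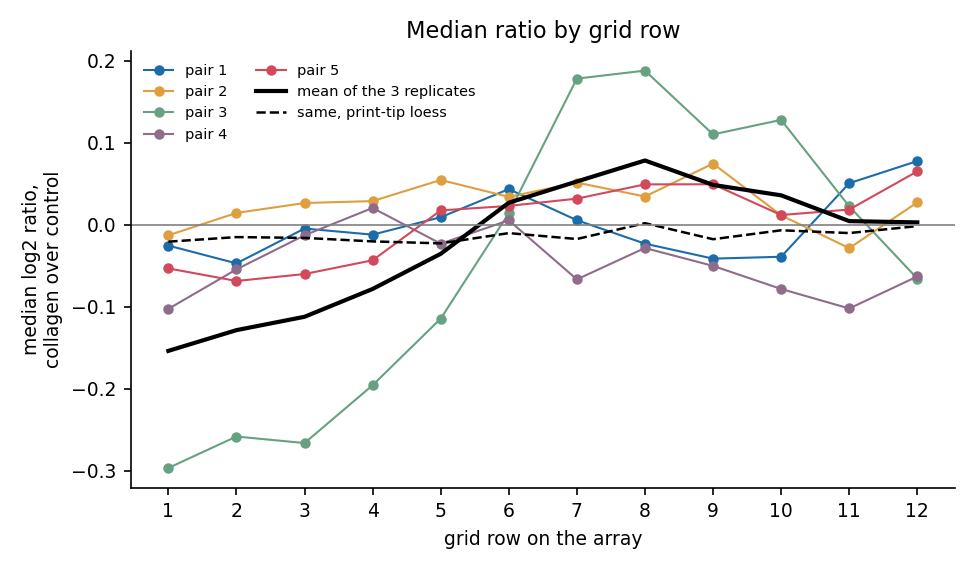
Median log2 ratio of collagen over control (y axis) in each of the 12 grid rows of the array (x axis). Thin lines are the 5 dye-swap pairs, the thick line the mean of the 3 replicates and the dashed line the same after print-tip loess. Pair 3 falls to -0.30 in row 1, and the dashed line lies between -0.02 and 0.00.

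The readings of Xist, the RNA that silences an X chromosome in female cells, differed between arms although all mice are labelled male. One Xist probe had the largest ratio of all tested probes, 1.09 (SD 0.89, n = 3), with an adjusted p of 0.642 by limma. It was higher in collagen on 7 of 9 arrays, with 2.07 in pair 1, 0.03 in pair 2, 0.89 in pair 3 and 0.62 in pair 5. On the only array of pair 4 that measured it, it read -0.20. The other Xist probe was measured in both channels on 6 arrays and was higher in collagen on all 6. Its log2 ratio was 4.30 in pair 3 and 5.81 in pair 4, and 1.71 and 1.73 on single arrays of pairs 1 and 5. It had no value in replicate 2 and so was not tested, and without replicate 2 limma called it (log2 ratio 5.06, adjusted p = 0.00354). Xist was singled out after its values were seen.

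**Figure D4:**
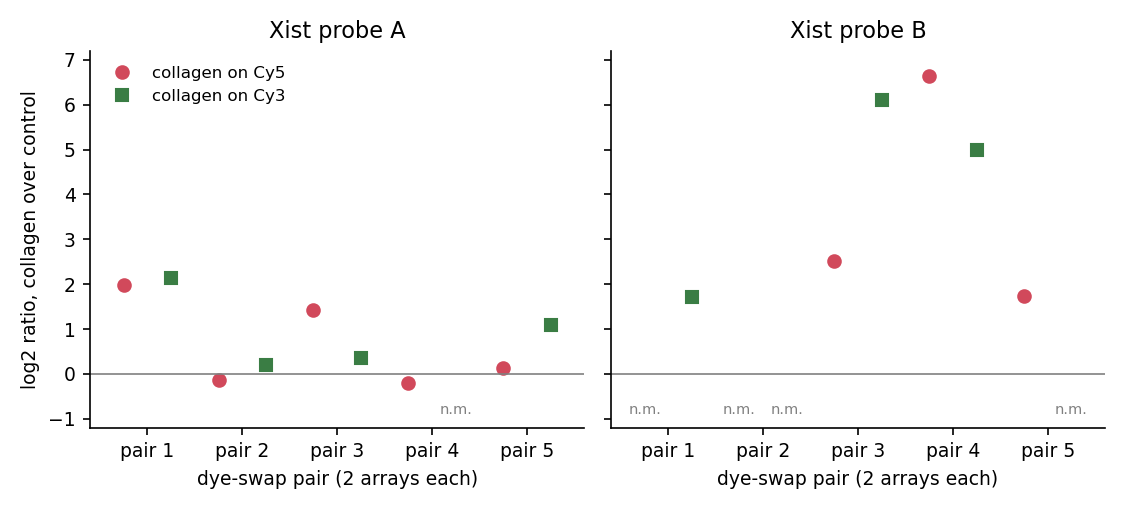
Log2 ratio of collagen over control (y axis) of the 2 Xist probes, A on the left and B on the right, on the 10 arrays ordered by dye-swap pair (x axis). Circles have collagen on Cy5 and squares collagen on Cy3, and n.m. marks arrays without both channels measured. Probe B is above 0 on all 6 arrays that measured it, up to 6.64.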

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

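The tests of position, of dye bias and of the single pair, and those of dye preference and of a faulty spot for Xist, were chosen only after the result was seen. Among 49 groups of values tested for a value far from the rest, 1 stood out, where chance gives about 1 in 20. It was the background of channel A over channel B on the array of pair 2 with collagen on Cy5, at 2.42, with the next highest of the 5 at 1.36.

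Outside the tested probes, an Xist probe read 4.30 on the log2 scale in pair 3 and 5.81 in pair 4, higher in collagen than in control. A dye preference of the probe is argued against, because collagen was higher on 6 of 6 arrays, 3 in each orientation. A single faulty spot stays open in both pairs. In pair 3 the other Xist probe read 0.89 (SD 0.74 over 2 arrays), past the bound of 1 SD above 0 chosen for the test. That is far under 4.30, and 2 arrays are too few to decide. In pair 4 that probe read -0.20 on the only array that measured it. RNA of female mice in some collagen samples stays open: genes that escape X inactivation lay at -0.0746 relative to all probes in pairs 3 and 4, under the bound of 0.05 set beforehand against it, but by less than their spread (SD 0.27 over 6 probes), a criterion tightened after the value was seen. The escape genes were divided: 2 probes of Ddx3x lay above 0 in both pairs, between 0.05 and 0.31, and Kdm5c below 0, at -0.53 and -0.09. The Y-linked gene Kdm5d, predicted lower in that case, read -0.84 in pair 3 and 0.33 in pair 4, but its sign followed the dye on all 10 arrays. Uty, also Y-linked, was measured on 3 single arrays, of pairs 1, 4 and 5. It read 0.23, 0.39 and 0.14, not lower, but on both arrays of no pair. An effect of collagen on Xist was not tested apart from these explanations.

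The ribosomal protein, oxidative phosphorylation and antioxidant sets are bright. A trend shared by genes of like brightness is argued against as the only cause. Loess had already fitted each reading for intensity, and random lists matched on intensity had medians of 0.013, 0.0005 and -0.005. The medians of the 3 sets lay at or above percentile 99.0 of 10000 such lists. Those lists do not carry the correlation among members, so their spread may be too narrow and the percentile does not measure chance. Position on the array is argued against as the whole cause, since with print-tip loess the medians were 0.10, 0.06 and 0.10 (ribosomal, oxidative phosphorylation, antioxidant) and the highest adjusted p was 0.0102, although 0.899 with an estimated correlation. With print-tip loess without replicate 3 the medians were smaller, at 0.068, 0.020 and 0.033, and none of the 3 sets passed (adjusted p = 0.0640, 0.680 and 0.596 by limma's camera). A dye effect shared by both arrays of a pair cancels in the mean and would give medians as low as the -0.12 seen with collagen on Cy3, so only a dye bias that differs between the arrays of a pair stays open, which the design cannot separate from collagen. Of the 4 ways to set the signs of the replicates, 2 gave 3 sets, the real one and that with replicate 2 turned (highest other 3), and 4 are too few for a share under 0.05.

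The larger part of the dependence on grid row fits uneven signal in pair 3. Without that pair the range of the row medians was 0.407 of its size with it, down to 0.09 from 0.23 on the log2 scale. With pair 3 included, 1000 shuffles of probes over rows gave at most 0.08, which bears on the 0.23 alone. On the array of pair 3 with collagen on Cy3 the row medians spanned 1.13, the widest of the 10 arrays. Whether genes printed in those rows changed with collagen stays open, since row medians correlated between pairs at 0.222 on average, between the bounds of 0.2 and 0.5 set beforehand. The single correlations ran from -0.166 to 0.824. Row 1 lay below 0 in each of the 5 pairs, from -0.01 in pair 2 to -0.30 in pair 3. That low row was therefore not confined to pair 3.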

How the results depend on the processing

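Of 31 alternatives 23 were chosen before the data were examined and 8 after: normexp (first chosen as the correction to use, and made an alternative later), all spots, the settings without pair 4, 5 or both 3 and 4, and print-tip loess without each replicate. Where no cause is named, the cause was not tested. The arrays' signal over background limits the probes tested, since both channels were needed. No count of probes past the adjusted threshold reached beyond 1 except 28 on arrays with collagen on Cy5 alone, 18 on Cy3 alone, where dye effects do not cancel, and 3 with print-tip loess without replicate 2, which were both Xist probes and Fap. It was 1 with scaling between arrays, 1 with the replicate block on 10 arrays, 1 in the authors' values and 0 to 1 without a replicate. The ratio of Fap turned to -0.07 with print-tip loess without replicate 3. For the 31 named genes, 531 of 707 values stayed within 1 SD, 173 moved, 3 passed the adjusted threshold and 24 had the other sign, leaving out the authors' values, whose scale is unsettled and in which Efhc2 also passed. Of the medians of gene sets, 657 of 848 stayed within 1 SD and 188 moved.

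The count at an unadjusted p under 0.05, 268 of 4125 probes (6.497%), was 173 with print-tip loess, 144 with median centring, 400 (9.697%) with no background correction, 344 (8.34%) with scaling between arrays, 140 of 4501 with print-tip loess without replicate 1 and 201 to 369 without a replicate. With fewer probes tested it was 110 of 1845 (5.96%) with probes above background on every array, 172 of 2785 (6.18%) with reading 2 alone, 116 of 2575 (4.50%) in the first 3 pairs, 172 of 2939 (5.85%) in the authors' values, 158 of 2778 (5.69%) without pair 4 and 119 of 2595 (4.59%) without pair 5. The share was also higher with 5 pairs as replicates (167 of 1845, 9.05%) and with the replicate block on 10 arrays (173 of 1845, 9.38%, or 147 and 7.97% with a dye term). It was 565 of 4725 on arrays with collagen on Cy5 alone and 887 of 6154 on Cy3 alone. The mean correlation between replicates was 0.0544 with print-tip loess, -0.00943 with median centring, 0.285 on Cy5 alone, 0.381 on Cy3 alone and 0.0567 in the authors' values. The dye effect's count was 255 with no background correction, 21 with median centring, 46 with probes above background on every array and 40 with normexp.

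The number of sets past the threshold, 3, was 0 with no background correction, on Cy3 alone, in the first 3 pairs, without pair 4, without pairs 3 and 4, with print-tip loess without replicate 3, with an estimated correlation and with fry, and 0 to 4 without a replicate. Ribosomal proteins, oxidative phosphorylation and antioxidant defence, in this order, had adjusted p-values of 0.154, 0.328 and 0.260 with no background correction, 0.313, 0.270 and 0.313 in the first 3 pairs, 0.316, 0.212 and 0.316 without pair 4, and 0.639, 0.911 and 0.911 without pairs 3 and 4. They were 0.0640, 0.680 and 0.596 with print-tip loess without replicate 3, 0.915 for each with an estimated correlation and 0.513 for each with fry. On Cy3 alone they were 0.287, 0.215 and 0.948, with medians turned to -0.12, -0.11 and -0.0480. Without a replicate they ran from 0.00277 to 0.333, 0.00277 to 0.543 and 0.0166 to 0.666.

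Antioxidant defence alone lost its call with median centring (0.509), probes above background on every array (0.154), reading 3 (0.218), 5 pairs as replicates (0.179), the replicate block (0.312, and 0.198 with a dye term), normexp (0.0816), without pair 5 (0.152) and with print-tip loess without replicate 1 (0.281). Glutamate signalling passed with scaling between arrays (0.0208), the dimmest probes left out (0.0372), reading 2 (0.0167), trend and robust eBayes (0.0215), the authors' values (0.0343) and the mean of a gene's probes (0.0491), and ran from 0.0346 to 0.357 without a replicate, but had 0.915 with an estimated correlation. Microglia passed with median centring (0.0292) and chemokines without pair 5 (0.0473). With an estimated correlation, run on the loess values of all pairs, the adjusted p was 0.915 for both. Plain background subtraction equals the values used and gave no comparison.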

Other observations

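Gene families other than the fixed sets were grouped by symbol after the single genes had been seen, and 17 of 18 had at least 5 measured genes. Some of their members, such as Slc1a3, Slc32a1 and Col1a2, also belong to a fixed set. Proteasome genes, which by symbol took in the assembly chaperones Psmg1, Psmg2 and Psmg3 beside the subunits, had the lowest p. Of these, 19 of 23 genes were higher, with a median log2 ratio of 0.12. Psmc4, an ATPase of the 19S cap, had 0.31 (SE 0.10), the activator subunit Psme3 0.36 (SE 0.17), Psma6 of the core 0.28 (SE 0.13) and Psmb2 of the core 0.19 (SE 0.10). The replicate medians were 0.02, 0.04 and 0.28, so replicate 3 held most of the shift. The hypothesis that families other than the fixed sets changed with collagen asked for at least 1 family past the threshold. By limma's camera 1 passed, the proteasome genes (adjusted p = 0.00233, and 0.0278 with print-tip loess, where the median was 0.070). With an estimated correlation its adjusted p was 0.953, and on that ground, added after the value was seen, the hypothesis stays open.

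Translation initiation factors were higher in 8 of 11 (median 0.13, adjusted p = 0.110 by limma's camera) and did not pass. Their members included Eif4e, the cap-binding factor, at 0.25 (SE 0.12) and Eif3d at -0.23 (SE 0.11). Testis genes of the Tex, Prm, Tnp and Spata series were lower in 11 of 13 (median -0.12, adjusted p = 0.128). With print-tip loess the medians of these 2 families were 0.077 and -0.079. Mitochondrial ribosomal proteins, unlike the cytoplasmic ones, were divided 17 and 16 with a median of 0.00 (adjusted p = 0.842). Whether the 2 kinds of ribosomal protein differ was not tested. Potassium channels had a median of -0.06 over 19 genes (adjusted p = 0.616) and solute carriers -0.01 over 57 (adjusted p = 0.842).

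At an unadjusted p under 0.05 the real signs gave 268 probes and the highest of the other ways to set the signs of the replicates gave 176, so that only the real 1 of the 4 ways reached that count. The 4 ways are too few for a share under 0.05.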
